A study of Bos taurus with 8 samples.

How the data were processed

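Gene expression was measured in pooled bovine (Holstein) blastocysts made in vitro. Per the labels, embryos were cultured under control conditions to the 8-16 cell stage on day 3. Lipids extracted from serum were then added to the culture medium of the treated embryos until the blastocyst stage on day 7. Control embryos received no lipids. Blastocysts were collected 170 hours after fertilization and pooled, 10 per pool, with 4 control pools and 4 lipid pools. Per the labels' protocols, total RNA was amplified in a linear T7 reaction, and the antisense RNA was coupled chemically to the dye Cy3 or Cy5. Each pair of a control and a lipid pool was hybridised on 2 arrays with the dyes exchanged, which gave 8 arrays on 2 slides, named 87 and 88 in the labels.

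The scanner files that the authors deposited hold, per the file headers, a mean foreground intensity and a median local background intensity for each spot at 532 nm (Cy3) and 635 nm (Cy5). The 14 rows of summary statistics at the end of each file and 8 spots without an identifier were dropped, which left 45212 spots and among them 43794 expression probes, each spotted once. The authors also deposited a table of processed values for the same arrays, whose unit was taken to be a log2 ratio. The submitters' processing notes name limma and no further step. Set against the scanner values, every column of that table ran as lipid over control, with a correlation of 0.950 to 0.980 across probes. Its column medians lay between -0.03 and 0.02, and its slope on the log2 ratios computed here was 0.858 to 0.892. Its log base, background correction and normalization are not given in the sources used here, and it served as an alternative only.

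The intensities were corrected for background with normexp (offset 50) on all spots and normalized by loess within each array, with control spots at weight 0 and no scaling between arrays, in limma 3.58.1 under R 4.3.3. Every array was turned to log2 lipid over control. A probe was kept if its foreground in either channel exceeded the mean plus 2 SD of the 757 negative control spots of that array on at least 4 of the 8 arrays. This left 28844 probes. On slide 87, array 1 had a few bright negative control spots, so its limits were high and 20.5% of its probes passed, against 55.2% to 73.8% on the other arrays. Saturated spots were kept, and numbered at most 18 in a channel. The number of arrays and the signal over background limit the precision: probe medians were 230 to 324 in Cy3 and 180 to 229 in Cy5, over local backgrounds of 19 to 22 and 36 to 58. Control probes spotted 10 times varied within an array by an SD of 0.13 to 0.55 in log2 ratio, most on arrays 1 and 4 of slide 88.

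The labels do not say which arrays hold the same pools. Array numbers 1 to 4 occur once on each slide with opposite dyes, and a rule fixed before the data were examined paired arrays by number if each pair deviated together from the means of its dye orientation. The correlations of these deviations were 0.61 to 0.77 for arrays of the same number and -0.32 to -0.03 for all others. The 2 arrays of a number were therefore averaged into 1 pool pair, so that n = 4 pool pairs and a dye effect common to both slides cancels in each. Whether the pools came from separate fertilization runs is not stated, so the tests measure the spread between these pools. A dye effect that differs between slides enters pool pairs 1 and 2 with the sign opposite to 3 and 4, because their dye orientations differ on each slide. It cancels in the mean over the 4 pool pairs but stays in single pool pairs and widens the SE, and a fit with a term for it was added as an alternative after seeing the data.

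The log2 ratios of the pool pairs were tested against 0 with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. Shifts of 21 gene lists were tested with camera (limma, preset inter-gene correlation 0.01, two-sided) on 11684 genes, each through its brightest kept probe, with adjustment over the lists and, as an alternative, with a correlation estimated for each list. The slides were compared through limma fits within each slide, with a treatment and a dye term. Gene lists, tests, most alternatives and the rule for naming genes were fixed before the data were examined. That rule names the 12 genes with the largest rise and the 12 with the largest fall past the threshold. Where fewer than 24 pass, it names the genes of smallest p up to 24, as values and not as changed. It also names up to 4 members of smallest p per list and 21 genes of lipid metabolism and lineage, of which 19 were measured. Below, 4 members are given for the cholesterol synthesis, interferon, glycolysis and cumulus lists, and fewer for the others. Other genes named below were chosen after their values were seen.

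Probe names come from the platform's annotation, in which 21790 probes have 1 gene symbol, 22004 have none and 0 have several. Of 15227 array symbols, 14139 are current in the cattle RefSeq table of assembly ARS-UCD2.0 and 1088 are synonyms there; the array's symbols are kept, except that list members are called by the list's name. No probe positions were used. Among the 2695 genes with more than 1 kept probe, the probes' log2 ratios spanned a median of 0.15, and 52.1% of these genes had probes of both signs.

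The steps were tested on simulated data before use on the arrays. For the serum lipid comparison, 10 simulated sets of 28844 probes were made, and 200 probes were changed in each. Their spread between pool pairs, array noise and dye effects were taken from the real probes. At this size the limma fit called 0.896% of probes changed 1.5-fold, 49.6% of those changed 2-fold and 84.8% of those changed 4-fold, with 14 false calls in all. The spread taken from the real pool pairs already held the dye effect that differs between slides, and the dye effects were then added again. The simulated spread between pool pairs was thus wider than the real one, and these shares do not carry over exactly to the arrays. The gene list sets were made the same way. For the gene list shifts, run on 11684 genes, a list moved by 0.3 in log2 was called in 10 of 10 sets and no other list was called. The simulated genes were drawn independently of each other, so these sets do not show how often lists of correlated genes are called falsely. The estimated inter-gene correlation of the real cholesterol list was 0.582. Alternatives covered the background correction, normalization, probe filter, array pairing, slide, variance prior, the authors' values, probe choice, inter-gene correlation, and leaving out each pool pair. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.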

Results

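The arrays compared bovine blastocysts that developed with serum lipids from day 3 to day 7 with blastocysts cultured without them. Serum is a common supplement of embryo culture, and its lipids, cholesterol and fatty acids among them, can be taken up by the embryo. The data comprised 8 two-colour arrays of 4 pool pairs, each a lipid pool and a control pool of 10 blastocysts on 2 arrays with exchanged dyes. Of 43794 probes, 28844 gave signal above background on enough arrays, and 15614 of these carried a gene symbol, for 11684 genes. Values below are mean log2 ratios of lipid over control ± SE over n = 4 pool pairs, unless a pool pair is named.

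The first question was which single genes differed between lipid and control blastocysts. No probe passed the threshold. The largest ratio among the 24 named genes of smallest p was that of XCL2, a chemokine, at 1.48 ± 0.24, or 2.79 times the control level, with 0.86 to 2.30 in the single pool pairs. NRIP1, a corepressor of nuclear receptors, had 0.96 ± 0.19. KCNRG, a regulator of potassium channels, had 0.63 ± 0.11, FYN, a kinase of the Src family, 0.60 ± 0.07, and ATG2B, an autophagy protein that moves lipid between membranes, 0.52 ± 0.07. The other ATG2B probes had 0.17 and -0.004. In the control channel, NRIP1 and FYN each passed the background limit on 3 of the 8 arrays and ATG2B on 2. On the lower side stood PRM1, a sperm protamine, at -0.79 ± 0.10 and ACP5, an acid phosphatase, at -0.69 ± 0.11. CGN (cingulin), a tight junction protein, had -0.74 ± 0.08. The other CGN probes had -0.27 ± 0.08 and, for the brightest, -0.24 ± 0.15.

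Others with negative ratios were ARRDC2 (-0.65 ± 0.10), CYP4A22 (-0.59 ± 0.08), of a family of fatty acid hydroxylases, and MMAB (-0.55 ± 0.10), which makes the active form of vitamin B12. KLHL20 had -0.50, LOC616431 -0.47, GTF2F2 (a subunit of a general transcription factor) -0.46, ADAL -0.45, CSNK2A2 (a catalytic subunit of casein kinase) -0.44, ZNF354A -0.37, ZNF250 -0.36, POT1 (a telomere-binding protein) -0.36 and LOC100295951 -0.34. Positive ratios were also measured for LANCL2 (0.48), RAB34 (0.47), ARHGEF2 (0.46) and ETV2 (0.37). The control channel of ETV2 passed the background limit on 1 of the 8 arrays. All 24 had the same sign in all 4 pool pairs, 9 higher and 15 lower with lipid, which the choice by smallest p favours. Over all kept probes 11.4% had one sign in all 4, below the 12.5% of independent pool pairs, which a dye effect that differs between slides would lower. Of the 10 that had more than 1 kept probe, 6 had probes of both signs, for example NRIP1 at 0.96 and -0.02.

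In the limma fit 0 probes passed an adjusted p of 0.05 (lowest adjusted p = 0.996), and 1287 probes (4.46%) had an unadjusted p under 0.05, 597 higher and 690 lower with lipid. That count depends on the fit: it was 196 with a trend and robust prior, 916 without pool pair 4 and 2314 without pool pair 1, with 0 called each time. With the pool pair as a random block and a dye term per slide, a fit added after seeing the data, it was 2365 (0 called, lowest adjusted p = 0.0668). Mean ratios of at least 1.5-fold were found for 98 probes in the upward and 87 in the downward direction. The ratios of different pool pairs were correlated across probes by -0.21 to 0.25, and probes are not independent replicates. With no replicate block, that is with the 8 arrays taken as independent, limma called 7 probes, among them PRM1, FYN and CGN, and 66 with a dye term for each slide. Those fits count the 2 arrays of one pool pair as separate samples.

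Cholesterol synthesis genes were lower in the lipid blastocysts on average over the pool pairs, but not in each of them. Of 20 measured members of the cholesterol synthesis and uptake list, 17 had negative and 3 positive ratios, with a median of -0.18, and the list passed the camera test (limma, adjusted p = 0.000944). With the inter-gene correlation estimated from the data, 0.582 for this list, it did not pass (camera adjusted p = 0.928). HMGCS1, which makes the precursor of mevalonate, had -0.62 ± 0.24, and MSMO1 (SC4MOL on the array), a sterol oxidase, had -0.56 ± 0.19. NSDHL, a sterol dehydrogenase, had -0.33 ± 0.10 and SC5D (SC5DL), a sterol desaturase, -0.19 ± 0.06. INSIG1, which holds the sterol-sensing complex in the endoplasmic reticulum, had -0.50 ± 0.35, and SQLE, the squalene epoxidase, -0.37 ± 0.17. HMGCS1 had 4 kept probes, all with negative ratios, from -0.68 to -0.12. The other probes of INSIG1 had -0.06 and -0.04, and those of MSMO1 -0.49, -0.32 and 0.02. No member passed the threshold over all probes or adjusted over the list alone.

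The shift was uneven among the pool pairs. All 20 members were below 0 in pool pair 2, where the median was -0.51, and 13 and 14 in pool pairs 3 and 4, with medians of -0.09 and -0.23. The single arrays of pool pairs 3 and 4 had medians above 0 on slide 87 (0.04 and 0.04) and below 0 on slide 88 (-0.11 and -0.35). In pool pair 1, 8 were below 0 and the median was 0.10. The fit gave a median of -0.11 on slide 87 alone, where only array 2 of the 4 was below 0, and -0.29 on slide 88 alone, with the list past the threshold on each. The call also ended without pool pair 2 (median -0.05, camera adjusted p = 0.725). In the lipid pool of pool pair 2, markers of cumulus and granulosa cells, which surround the oocyte in the follicle, were also higher, with a median of 0.74.

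**Figure D1:**
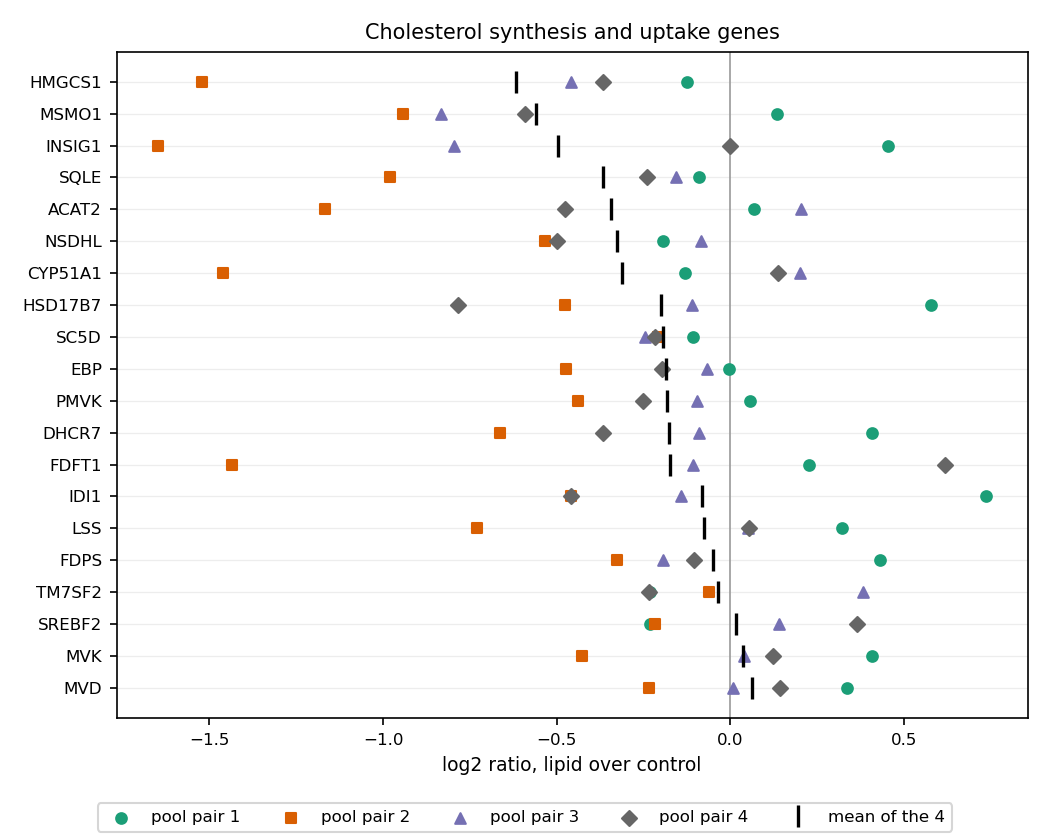
Log2 ratio of lipid over control (horizontal axis) of each of the 20 measured cholesterol synthesis and uptake genes (vertical axis). Points are the 4 pool pairs, each the mean of 2 dye-swapped arrays, and bars are their mean; all 20 points of pool pair 2 lie below 0, with HMGCS1 at -1.52 there.

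No other list of lipid genes passed the threshold. In the fatty acid synthesis and desaturation list, 8 of 17 members were above 0, with a median of -0.00 (camera adjusted p = 0.877). SCD5, a stearoyl-CoA desaturase, had 0.69 ± 0.24, ELOVL1 0.21 ± 0.14, SCD -0.18 ± 0.18 and FASN, the fatty acid synthase, 0.00 ± 0.08. The lipid droplet and triglyceride list had 10 of 19 members above 0 and a median of 0.00 (adjusted p = 0.928). There FITM2, a protein of droplet formation, had -0.24 ± 0.08, AGPAT1 0.16 ± 0.07 and PLIN2, a droplet coat protein, -0.05 ± 0.20. In the list of fatty acid uptake, binding and activation, 10 of 15 were below 0, with a median of -0.02 (adjusted p = 0.678), ACSL1 at -0.20 ± 0.08, ACSL6 at 0.22 ± 0.10 and FABP3, a fatty acid binding protein, at -0.13 ± 0.11.

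Of 20 genes of fatty acid oxidation and PPAR targets, 12 were above 0, with a median of 0.01 (camera adjusted p = 0.867). PPARD, a fatty acid-sensing nuclear receptor, had 0.23 ± 0.08, CPT1A, which admits fatty acids to mitochondria, 0.14 ± 0.09, PDK4 -0.10 ± 0.20 (other probe 0.26) and ANGPTL4 0.05 ± 0.07. Cholesterol efflux, storage and lipoprotein genes had 12 of 17 members above 0 and a median of 0.03 (adjusted p = 0.142). Its medians in pool pairs 1 to 4 were 0.04, 0.06, 0.05 and 0.06, with 5, 5, 4 and 7 members below 0 (camera unadjusted p = 0.0405). The glycolysis, antioxidant and cumulus lists, which did not pass either, had smaller camera unadjusted p (0.0181, 0.0318 and 0.0336). NR1H3, the oxysterol receptor LXR alpha, had 0.40 ± 0.15, with a dimmer probe at -0.11 ± 0.06 that was below 0 in all 4 pool pairs, and APOM had 0.29 ± 0.12.

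Interferon response genes were higher with lipid on average over the pool pairs, most of it from pool pair 2. Of 17 measured members 14 were above 0, the median was 0.27, and the list passed the camera test (limma, adjusted p = 0.00397). With an estimated inter-gene correlation it did not pass (camera adjusted p = 0.729), and cumulus and granulosa markers were higher in pool pair 2 as well. STAT2, which carries the interferon signal to the nucleus, had 0.43 ± 0.18, ISG15, a ubiquitin-like protein, 0.25 ± 0.12, and IFNT, the interferon of the ruminant trophectoderm, 0.27 ± 0.22. The member of smallest p went the other way: IRF7, a transcription factor that induces interferon genes, had -0.39 ± 0.09 and was below 0 in all 4 pool pairs. RSAD2 was not well above background in the control channel on any of the 8 arrays and in the lipid channel on 4, and no fold is given for it. No member passed the threshold, over all probes or adjusted over the list alone.

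The interferon median was 0.81 in pool pair 2, the pool pair in which the cumulus and granulosa markers stood at 0.74, and -0.06, 0.07 and 0.18 in pool pairs 1, 3 and 4. It was 0.24 on slide 87 alone, where the list passed, and 0.18 on slide 88 alone, where it did not (camera adjusted p = 0.249). The call also ended without pool pair 2 (median 0.09, camera adjusted p = 0.0967) and without pool pair 4 (median 0.30, adjusted p = 0.0716). Requiring signal above background on all 8 arrays, including array 1 of slide 87 with its high limits, left 3 members, and the call ended there with a median of 0.27 (camera adjusted p = 0.949).

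**Figure D2:**
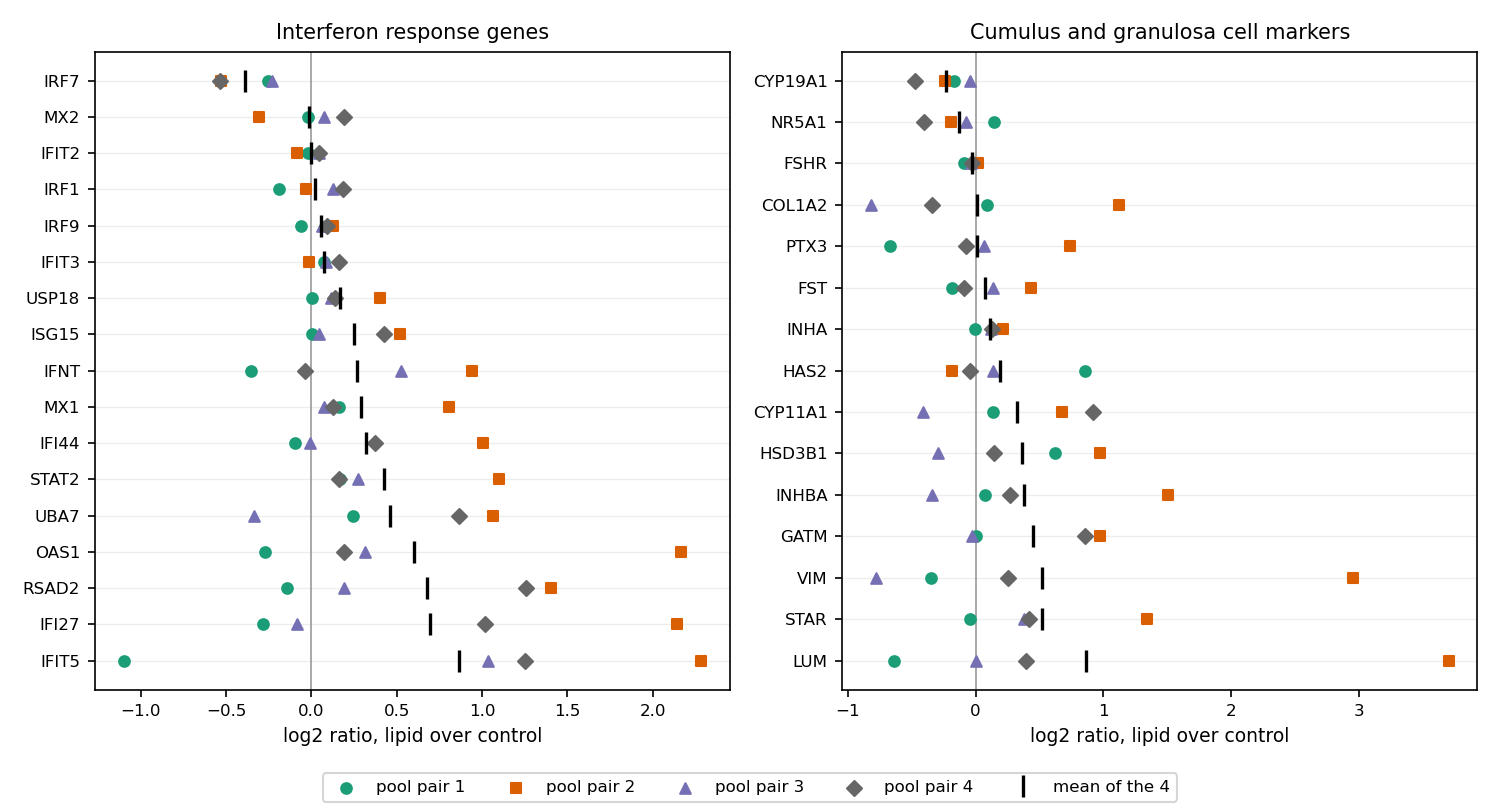
Log2 ratio of lipid over control (horizontal axes) of the 17 measured interferon response genes (left) and the 15 measured cumulus and granulosa cell markers (right). Points are the 4 pool pairs and bars their mean; pool pair 2 holds the highest points, such as OAS1 at 2.16 and LUM at 3.70, and RSAD2 and IFI44 were not well above background in the control channel on any array.

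Among genes of energy metabolism, several of glycolysis had positive ratios in each pool pair through their brightest probes, while the list did not pass. SLC2A1, the glucose transporter GLUT1, had 0.36 ± 0.09, PDK1, a kinase that holds back pyruvate oxidation, 0.31 ± 0.08, TPI1, a glycolytic isomerase, 0.66 ± 0.18, and LDHA, a lactate dehydrogenase subunit, 0.34 ± 0.10. Of the 17 measured members, 9 were above 0, with a median of 0.04 (camera adjusted p = 0.127). Dimmer probes did not all follow: that of SLC2A1 had -0.01 ± 0.19, and that of PDK1 0.09 ± 0.08, with -0.04 in pool pair 1. Oxidative phosphorylation genes had 12 of 22 members above 0 and a median of 0.02 (adjusted p = 0.867), with NDUFB5 at 0.20 ± 0.08 and COX6A1 at 0.20 ± 0.10.

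Stress and growth lists did not pass either. In antioxidant defence, 18 of 24 genes were above 0, with a median of 0.08 (camera adjusted p = 0.141), PRDX2 at 0.26 ± 0.11 (other probe -0.06), GPX3 at 0.26 ± 0.13 and GPX4, which removes lipid peroxides, at 0.15 ± 0.10. For the endoplasmic reticulum stress response 11 of 19 were below 0, with a median of -0.02 (adjusted p = 0.867), CHAC1 at -0.16 ± 0.10, DNAJC3 at -0.35 ± 0.23 and the chaperone HSPA5 at 0.18 ± 0.12. Inflammatory signalling had 11 of 20 above 0 and a median of 0.01 (adjusted p = 0.928), with NFKBIA, an inhibitor of NF-kappaB, at 0.29 ± 0.10 and IL6 at -0.37 ± 0.15. Apoptosis genes had 10 of 16 below 0 and a median of -0.02 (adjusted p = 0.867), with TNFRSF1A, a receptor of tumour necrosis factor, at 0.80 ± 0.29 and BID at -0.21 ± 0.09. Cell cycle genes had 13 of 23 above 0 and a median of 0.02 (camera adjusted p = 0.913). PCNA had -0.21 ± 0.11 (other probes -0.08 to -0.04) and MCM2 0.32 ± 0.17 (other probe 0.23).

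No list of lineage markers of the blastocyst passed the threshold. Trophectoderm markers had 11 of 19 members above 0 and a median of 0.03 (camera adjusted p = 0.671). PTGS2 had 0.22 ± 0.12 (other probes 0.23 and -0.03), ID2 0.21 ± 0.11, CDX2, a transcription factor of the trophectoderm, -0.04 ± 0.07, and KRT18, a keratin, -0.05 ± 0.28. Of the inner cell mass and epiblast markers 9 of 17 were above 0, with a median of 0.01 (adjusted p = 0.867). There the pluripotency factors POU5F1, NANOG and SOX2 had -0.19 ± 0.09, 0.14 ± 0.19 and -0.04 ± 0.10, and ESRRB had -0.25 ± 0.08. Primitive endoderm markers had 11 of 17 above 0 and a median of 0.04 (camera adjusted p = 0.867). HNF4A had -0.41 ± 0.17 (other probe -0.07) and COL4A1 -0.22 ± 0.10. LAMA1 and RSPO3, of the same list, went the other way, at 0.48 ± 0.27 and 0.27 ± 0.15. Genes of blastocoel formation and cell junctions had 10 of 18 below 0 and a median of -0.04 (adjusted p = 0.877), with CLDN7 at -0.20 ± 0.07 and CTNNB1 (beta-catenin) at 0.33 ± 0.12.

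Markers of cells that could accompany the embryos were measured as well. Cumulus and granulosa cell markers had 12 of 15 members above 0 and a median of 0.19, which missed the threshold (camera adjusted p = 0.141), with medians of -0.00, 0.74, -0.03 and 0.13 in pool pairs 1 to 4. STAR, which brings cholesterol into mitochondria for steroid synthesis, had 0.52 ± 0.23 (other probes 0.28 and -0.05), GATM 0.45 ± 0.21 and INHA 0.12 ± 0.07. CYP19A1, the aromatase, had -0.23 ± 0.09 (other probe -0.60). Sperm and testis markers had 7 of 9 below 0 and a median of -0.07 (adjusted p = 0.145), with PRM1 as above and CABYR at 0.15 ± 0.09. PRM1 was the single gene of any list past the threshold when adjusted over the list alone (limma adjusted p = 0.00278). Blood cell markers had 4 of 7 above 0 and a median of 0.01 (adjusted p = 0.877), with CD68 at 0.21 ± 0.10 and CD74 at -0.11 ± 0.06.

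Of the 21 lists, 2 passed the threshold with the preset correlation and 0 with estimated correlations (lowest adjusted p = 0.696). Median, mean and test did not share 1 sign for the lists of fatty acid synthesis, lipid droplets, apoptosis, blastocoel and junctions, and inner cell mass, and all 5 had medians near 0.

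**Figure D3:**
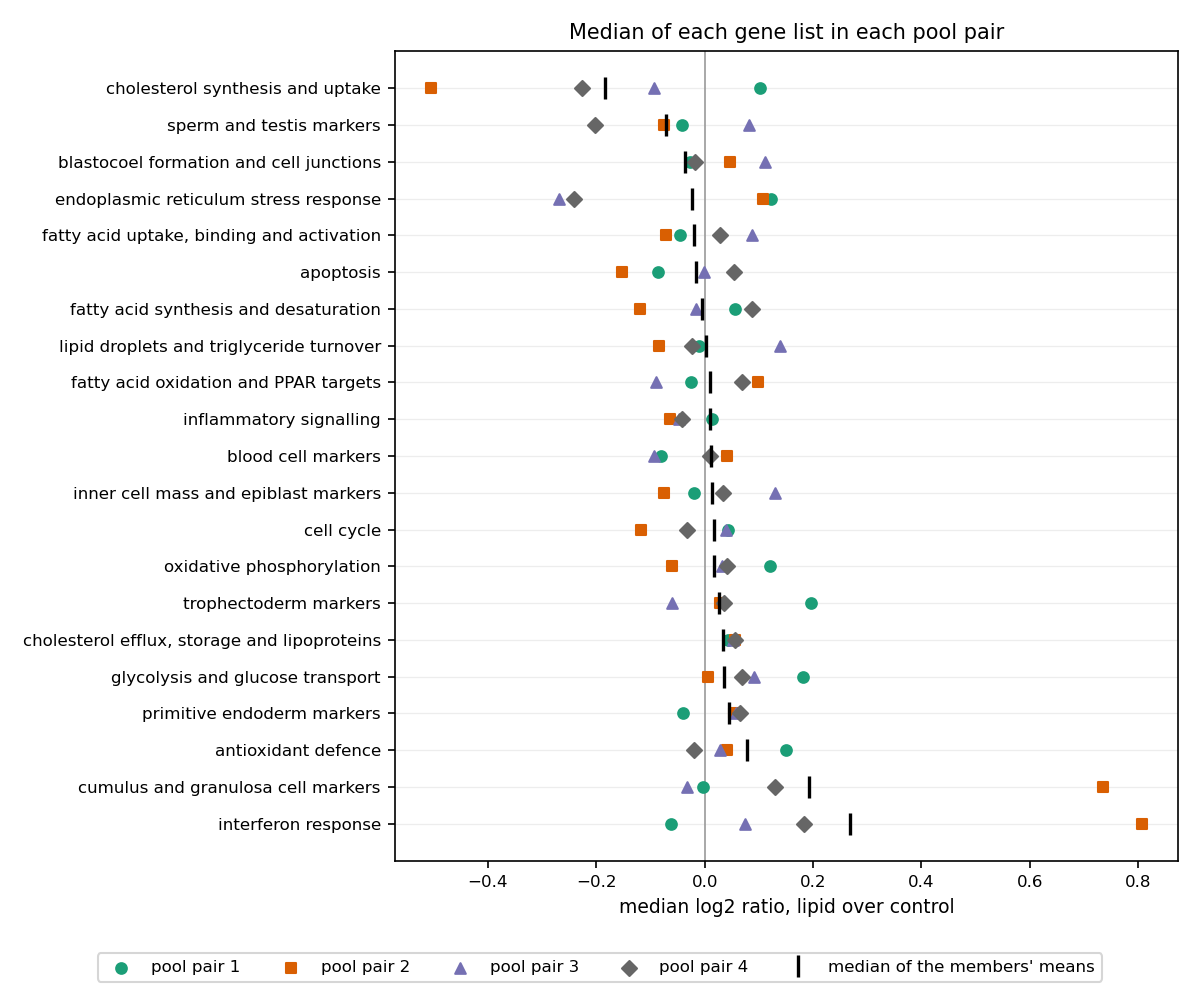
Median log2 ratio of lipid over control (horizontal axis) of each of the 21 gene lists (vertical axis). Points are the medians in the 4 pool pairs and bars the medians of the members' means; pool pair 2 lies lowest for cholesterol synthesis (-0.51) and highest for interferon response (0.81) and cumulus and granulosa markers (0.74).

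The slides, which carry the same pools under opposite dyes, were compared to see how well the gene ratios repeat. The log2 ratios of slide 87 and slide 88 were correlated across probes by 0.568, and 60.9% of probes had the same sign on both, after a dye term was fitted on each. Without one, the 2 arrays of a pool pair were correlated by 0.130, 0.376, 0.0571 and 0.120 in pool pairs 1 to 4. For the 24 named genes of smallest p, among them CGN, FYN and XCL2, the correlation was 0.961, but these genes were picked from the mean of both slides. Neither slide alone gave a probe past the threshold in limma, with 1450 and 2776 probes at an unadjusted p under 0.05. Because the pools recur on both slides, this measures technical repeatability, and not the spread between pools.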

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

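The 4 pool pairs were searched for one that stood apart from the rest, in 111 sets of values, and chance would single out about 1 set in 20. A pool pair stood apart in 9 sets, and in 5 of them it was pool pair 2. The dye tests below and the test on a like rise in every pool were chosen only after the results were seen.

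In pool pair 2, 425 probes were at least 2-fold higher with lipid, against 94 to 101 in each of the others. Single genes stood apart there too. STAT2 had a log2 ratio of 1.10, against 0.16 to 0.28 elsewhere. SQLE had -0.98, against -0.24 to -0.09, and SCD had -0.86, against -0.03 to 0.12. KLHL20 had -0.30 in pool pair 2, against -0.59 to -0.55. Elsewhere, ACP5 had -0.34 in pool pair 3, against -0.86 to -0.77. In pool pair 4, ETV2 had 0.24, against 0.41 to 0.44, and COX6A1 had 0.52, against 0.05 to 0.12. The median of the primitive endoderm markers was -0.0396 in pool pair 1 and 0.05 to 0.07 in the others.

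Cumulus and granulosa cell markers were higher in the lipid pool of pool pair 2, with LUM at 3.70, VIM at 2.96, STAR at 1.34 and COL1A2 at 1.12. Of the 15 measured, 12 were above 0 there and 5 at least 2-fold higher. The aromatase CYP19A1 went the other way, at -0.24 (other probe -0.61), and INHA had 0.22. Dye bias would turn the sign between the arrays of this pool pair, and the lower of the medians on its 2 arrays was 0.75. Lipids raising the markers to a like degree in every lipid pool would need similar medians elsewhere. The highest was 0.13, below pool pair 2 by 0.61, more than the members' SD of 0.41. That SD is the spread of genes within a pool pair and not of medians between pools. Chosen after the values were seen, the comparison describes the gap and does not test it. A second list of stromal and granulosa genes, 24 measured, did not settle what lay behind the higher markers. It left open somatic cells carried into the lipid pool of pool pair 2 or a smaller rise in every lipid pool. Over the pool pairs its median was 0.10, with 17 of 24 genes above 0 (camera unadjusted p = 0.0102, and 0.274 with an estimated correlation). The median was 0.24 in pool pair 2, where 0.5 was set as the mark for carried cells, and 0.14 and 0.09 in pool pairs 3 and 4. In pool pair 1 it was -0.16, with 17 of 24 genes below 0, which goes against a rise in every pool, though a single pool pair gives no spread to judge it by. In pool pair 2, 18 of 24 were above 0, among them SERPINE2 (1.55) and TIMP1 (1.10), while the abundant LGALS1 (-0.08) and MYL9 (-0.62) were not; control pools also gave signal for 17 of the 24 genes and for 11 of the 15 markers.

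Cholesterol synthesis genes had a median of -0.51 in pool pair 2, -0.09 and -0.23 in pool pairs 3 and 4, and 0.10 in pool pair 1, where 8 of 20 were below 0. Dye bias is argued against in pool pair 2, where the higher of the medians on its 2 arrays was -0.52. An intensity-dependent error of the loess normalization is argued against as well, since median centring in its place gave -0.17. Of 10000 random lists matched on intensity, 0 percent had a median as low. Loess centres such lists near 0 in any case, so they add little. Dye bias in pool pairs 3 and 4 stays open: their medians were 0.0415 and 0.0358 on slide 87 and -0.11 and -0.35 on slide 88, where the dyes were exchanged. Dilution by somatic cells in the lipid pool of pool pair 2 as the whole cause stays open in part. There 0 percent of matched lists were as low, and the lowest had -0.27. Loess would remove a fall shared by most genes from the cholesterol genes as well, so such a fall does not account for them. Genes that somatic cells also make would not fall by dilution, and the matched lists do not set these apart. In pool pair 2 the trophectoderm markers had a median of 0.03 and the inner cell mass markers -0.08, above the cholesterol genes. Bright markers went both ways there, with KRT18 at -1.05, NANOG at -0.53 and IFNT at 0.94. Also open is a difference between the pools unrelated to lipid, since without pool pair 2 the median was -0.05 and 16.5% of matched lists were as low. A response of the embryos to lipid, the difference the design names, was not separated from that.

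Turning the sign of whole pool pairs gives 8 arrangements, too few for a share under 0.05. The limma fit called 0 probes in the real arrangement and at most 0 in the others. With 0 in the real arrangement, all 8 had to give as many, so the probe count can decide nothing here. For the gene lists, such as cholesterol synthesis and interferon response, 2 passed in the real arrangement and at most 4 in another, and 5 of the 8 gave as many.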

How the results depend on the processing

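Of 21 alternatives for the count of probes past the threshold, 19 gave 0 in limma. Some of these could give no other count once the main fit gave 0. A further limit of 1.5-fold and the largest p over all 24 pairings of the arrays can only remove probes, and scaling between arrays left the ratios unchanged. The fits with the pool pair as a random block, with a slide-specific dye term and with limits from 1 kind of control spot were added after seeing the data. With no replicate block, limma called 7 probes (1 higher and 6 lower with lipid), and with a dye term per slide on the same 8 arrays 66 (24 higher and 42 lower), since both count paired arrays as independent. Leaving out each pool pair gave 0 throughout. The number of lists past the threshold was 1 with signal required on all 8 arrays, 1 on slide 88 alone, 3 on slide 87 alone (where the cumulus markers passed too), 0 with estimated correlations, and 0 to 5 when leaving out each pool pair; the pool pair's absence was the sole change there, and the cause was not tested further. The 0 came without pool pair 2 and the 5 without pool pair 3, when glycolysis, cumulus and sperm markers passed too. Several alternatives for the lists, such as another variance prior or an estimated correlation, leave the ratios unchanged, so the sign was fixed there. The cholesterol list stayed below 0 in all 22 alternatives and passed in 20 (camera adjusted p 4.31e-06 to 0.928). Its median was -0.18 with an estimated correlation, and -0.33 to -0.0482 when leaving out each pool pair, the last without pool pair 2. The interferon list stayed above 0 in all 22 and passed in 17 (adjusted p 0.000457 to 0.949). Its median was 0.27 with signal required on all 8 arrays and with an estimated correlation, 0.18 on slide 88 alone and 0.0890 to 0.34 when leaving out each pool pair, the first without pool pair 2. With signal required on all 8 arrays, 2 other lists had no member left and gave no value. The agreement of the slides, a correlation, was 0.456 with no filter, where dim probes enter, and 0.547 (without replicate 2) to 0.717 (without replicate 1) when leaving out each pool pair. Other calls were unchanged. Of 826 values of named genes under alternatives, 7 changed sign, 0 of them among the 24 genes of smallest p. These 24 had one sign in every pool pair, so leaving out a pool pair could not change it. Taking the 8 arrays as independent gives the same mean, so for these genes only the background and centring alternatives could change a sign.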

Other observations

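Beyond the fixed lists, the lipid pool of pool pair 2 had high ratios for several genes that were chosen here after their values were seen and not tested as a group. PLAT, the tissue plasminogen activator, had a log2 ratio of 2.99, TNN, a tenascin, 2.80, IGFBP7 2.65 and CDH2 (N-cadherin) 2.42, and each of these was at least 2-fold higher on both dye-swapped arrays of the pool pair. In the other pool pairs, in order 1, 3 and 4, PLAT had -0.58, 0.57 and 0.90, TNN -0.45, 0.46 and 1.08, IGFBP7 0.15, -0.48 and -0.24, and CDH2 -0.22, -0.15 and 1.29. At the lower end of pool pair 2 stood cholesterol genes, CYP51A1 at -1.46 and FDFT1 at -1.43, and SLC25A1, the mitochondrial citrate carrier, at -1.48.

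Across probes, pool pairs 3 and 4 were correlated by 0.25 and pool pairs 1 and 3 by -0.21. Pool pair 4 had more probes at least 2-fold lower (258) than higher (94) with lipid, but 73 and 44 when both dye-swapped arrays had to show it. Dye effects were called by limma for 1606 probes on slide 87 and 4994 on slide 88.

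SLC2A1, PDK1, TPI1 and LDHA, above 0 in all 4 pool pairs through their brightest probes but not through the dimmer probes of SLC2A1 and PDK1, are known targets of the hypoxia response, and a candidate explanation is that hypoxia-responsive genes were higher in the lipid pools. A list of other such genes, set down before their values were seen, was tested. Its median over 23 measured genes was 0.0369, with 15 above 0, and the camera unadjusted p was 0.241. CA9 had 0.38 ± 0.10 and NDRG1 0.28 ± 0.10, while PFKFB4 had -0.36 ± 0.22 and P4HA1 -0.28 ± 0.18 (SE, n = 4). That lies between the marks set for a shift (above 0.1 with a camera p under 0.05) and against it (at most 0.03), so the test left the question open.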
